A study of Arabidopsis thaliana with 16 samples.

How the data were processed

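Whole rosettes of 3 Arabidopsis genotypes in 2 light levels were measured on 16 Affymetrix gene arrays, 12 of single replicates and 4 of pooled RNA. Per the submitters' processing notes, the authors computed the deposited log2 signal values with RMA in Affymetrix Expression Console. The software version, the probe set library and the genome build were not given in the sources used here. The table of these values gives 2 decimals for 28501 probe sets, of which 28403 in the main category were analysed; 77 rescue probe sets and 21 for ribosomal RNA were left out. A workbook from the authors gives annotation, group means, ratios and p-values for 6 comparisons. The deposited p-value columns come from the authors' own tests per the file headers, with no adjustment named, and were used only for counts. The group means were used only for finding which arrays each mean averages. The 16 signal columns of the workbook could not be matched to the labels with certainty and were not used.

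Locus identifiers and symbols came from the authors' annotation and a RefSeq gene table. Of the analysed probe sets, 27582 carried 1 locus, 0 several and 821 none, and 27224 loci were represented, 292 of them by several probe sets. For 241 probe sets a locus on another chromosome than the probe set was dropped, and 148 that lie elsewhere on the chromosome than their locus in the RefSeq table are not named after it. Coordinates and GO terms are those of the authors' annotation, whose build is not given in the sources used here. The authors' annotation marks 990 probe sets as cross-hybridising with other transcripts, and members of gene families with near-identical sequence cannot be separated on them. Numbers in the text for loci with several probe sets use the one with the highest mean over the 12 arrays.

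Single-replicate arrays were fitted with limma (lmFit and eBayes, 4 group means, default prior, two-sided) and Benjamini-Hochberg adjustment over all probe sets, calling an adjusted p under 0.05. The comparisons, tests, gene lists, alternatives and the rule for naming genes were chosen before the data were examined, apart from those said to be added later. Pools were compared by the log2 difference alone, with a size of at least 1, since each group has 1 array. Against WT, a pool was also asked to lie outside the range of the WT pool and the WT replicates, and the same differences between WT arrays were counted beside it.

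The 27 gene lists covered ROS and stress regulators, AP2/ERF factors, heat shock, photoprotection, antenna, photosystem subunits, the Calvin-Benson cycle, tetrapyrrole synthesis, antioxidant enzymes, flavonoid synthesis, HY5 signalling, shade, sugar starvation, circadian clock, jasmonate, salicylate, abscisic acid, the SAP family, calmodulins, cytosolic ribosomal proteins, translation and TOR signalling, plastid ribosomal proteins, root, flower and guard cell markers, mitochondria-encoded genes and plastid-encoded genes. The last had fewer than 5 named members on the array and was not tested, which left 26. Lists were tested with limma's camera (preset correlation 0.01) and, as alternatives, camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way. Adjustment was over the lists within a comparison. Adjusted p-values given for lists are those of camera unless another test is named. For pools, the list median was placed among 10000 random lists matched on mean expression in 50 bins.

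Genes were named by rule: SAP3 and CML49 in every array, then per comparison the 10 largest increases and 10 largest decreases among the called probe sets with 1 locus and no overlap between the groups, up to 4 members per list with the smallest adjusted p, the 5 smallest p-values of an interaction with fewer than 5 calls, and in the pools the 10 largest differences each way among probe sets with 1 locus and a mean at or above the median, and between genotypes outside the WT range. Genes named outside this rule are said to be chosen after their values were seen.

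A light score was added after the first look at the data. It used 250 probe sets, 164 higher and 86 lower in HL by at least 2 in both pool pairs, and gave each array the median position between the LL pools (0) and the HL pools (1), with 0.5 as the midpoint. The arrays whose score opposed their label were left out in an alternative with 9 arrays, on which all comparisons were repeated. GO terms with at least 10 loci were tested for enrichment among the probe sets called in the 9 arrays by a one-sided Fisher's exact test against 17977 loci that carry a term, with Benjamini-Hochberg adjustment over 846 terms.

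Alternatives were a mean-dependent prior, a robust prior, array weights, a replicate block, median centring, a new quantile normalisation, removal of dim probe sets (highest group mean, or in the pools the mean, below the median of 4.39), 1 probe set per locus, an adjusted p under 0.01, only the groups compared, and leaving out each array. The fit was tested on simulated data in which 200 of 28403 probe sets were changed, 50 for each size. A log2 change of 1 was recovered in 86% of them for the WT and sap3 light comparisons and for the LL genotype comparison, 96% for the HL genotype comparison and 36% for the interaction with 12 arrays, and in 78%, 56%, 72%, 62% and 10% with 9. False calls numbered 4 to 11. The simulated spread was that of the real probe sets apart from the 3 arrays with an opposing light score. The recovery given for 12 arrays thus leaves out the spread that these 3 arrays add, and does not apply to the real fit of the 12 arrays. Computation used R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.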

Results

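Transcript levels were measured in whole rosettes of Arabidopsis thaliana on Affymetrix gene arrays, which carry short probes along each annotated transcript and were hybridised with biotin-labelled sense-strand cDNA. The genotypes were the wild type Col-0 (WT), a knockout of SAP3, which encodes a stress-associated protein with A20 and AN1 zinc fingers, and a knockout of CML49, which encodes a calmodulin-like calcium sensor. Plants grew for 3 weeks at 80 to 100 µmol photons per square metre and second, spent 10 days at 8 µmol (low light, LL), and were then harvested either in low light or after a transfer to 800 µmol (high light, HL). The length of the transfer is not settled, since the titles and the design text give 60 min and the treatment protocol gives 10 min. The labels name 12 arrays of single replicates, 3 for each of WT and sap3 in LL and HL, with 15 plants per replicate, and 4 pooled arrays of 45 plants each, 1 for each of WT and cml49 in LL and HL, which combine 3 replicates. The series title places the study in the acclimation of plastids and nucleus to high light, and the comparisons ask how the step in light changes transcript levels and whether the loss of SAP3 or CML49 alters that change. Values are log2 signals, with array medians of 4.37 to 4.41 and single values from 0.55 to 14.11, and the number of arrays limits the precision. P-values measure the spread between samples as the labels describe them, each replicate being 15 plants. Arrays are named by genotype, light and replicate as labelled, for example WT_HL_2.

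The genes disrupted in the mutants departed from the labels in some arrays. SAP3 (AT2G27580, chromosome 2, 11776411 to 11777529; genome build not given in the sources used here) had a log2 signal of 4.85, 4.84 and 5.14 in the arrays labelled WT in LL. Its values were 6.14, 3.94 and 6.48 in the arrays labelled WT in HL. The arrays labelled sap3 gave 4.21, 6.98 and 4.05 in LL and 5.06, 5.28 and 3.74 in HL. Group means were 4.94 ± 0.17 and 5.52 ± 1.38 for WT in LL and HL, and 5.08 ± 1.65 and 4.69 ± 0.83 for sap3 in LL and HL (SD, n = 3 each). The array with the highest SAP3 signal was thus labelled sap3_LL_2, and WT_HL_2 lay below all arrays labelled WT in LL. CML49 (AT3G10300, chromosome 3, 3186314 to 3188205) ranged from 4.14 to 4.54 over the 12 single-replicate arrays (mean 4.36 ± 0.13, SD, n = 12). It was lower in the pools labelled WT, at 2.77 in LL and 3.30 in HL, than in the pools labelled cml49, at 3.97 and 4.23. Because SAP3 departed from the labels in sap3_LL_2 and WT_HL_2 and CML49 in the pools, every group is called by its label throughout, and each direction given between groups is one between labels. Where the insertions lie relative to the probe sets is not given in the sources used here, so the remaining signal in a mutant is no measure of transcript loss.

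Light-responsive genes placed 3 single-replicate arrays on the side of the other light level. HSP90.1 (AT5G52640, chromosome 5, 21352399 to 21355361), a heat-inducible cytosolic chaperone, had 2.80 to 3.55 in the arrays labelled WT in LL and 9.80 and 9.77 in WT_HL_1 and WT_HL_3, but 3.62 in WT_HL_2. In the arrays labelled sap3 it had 3.86 and 3.19 in LL replicates 1 and 3 and 10.21 and 10.07 in HL replicates 1 and 2, but 11.09 in sap3_LL_2 and 3.17 in sap3_HL_3. A light score over 250 probe sets chosen on the pools alone, scaled to 0 for the LL pools and 1 for the HL pools, was 0.07 in WT_HL_2, 0.95 in sap3_LL_2 and 0.03 in sap3_HL_3. The other single-replicate arrays scored 0.03 to 0.06 where labelled LL and 0.92 to 1 where labelled HL. No array was relabelled. All comparisons were made on the 12 arrays as labelled, and were repeated without these 3 arrays, an alternative chosen after seeing the data that left 3, 2, 2 and 2 arrays for WT in LL, WT in HL, sap3 in LL and sap3 in HL. Since arrays were left out by their light level, the number of light-responsive genes in the 9 arrays is not independent evidence of a light effect.

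**Figure D1:**
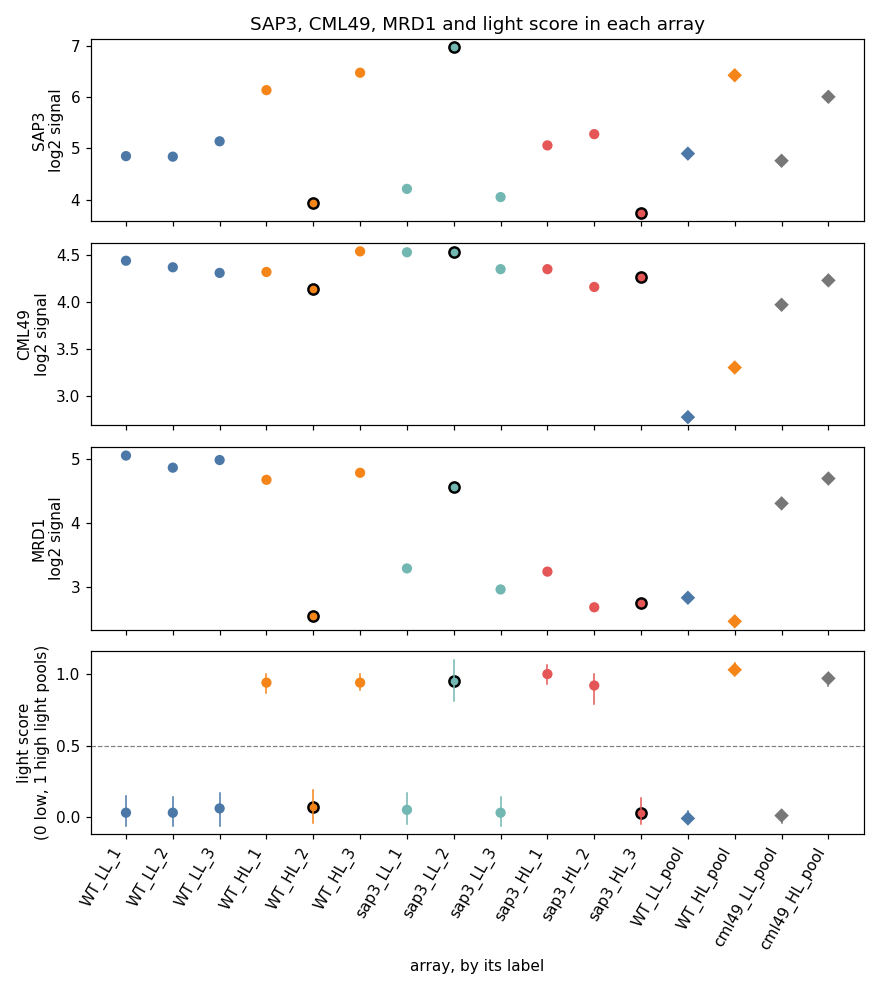
Log2 signal of SAP3, CML49 and MRD1 and the light score (0 for the low light pools, 1 for the high light pools; bars span the quartiles of 250 probe sets) in each of the 16 arrays, with pools as diamonds and the 3 arrays whose score opposes their light label outlined in black. The outlined arrays score 0.07, 0.95 and 0.03, and CML49 is lowest in the pools labelled WT, at 2.77 and 3.30.

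In the arrays labelled WT, genes of the heat shock response stood higher as a set in HL than in LL, and genes of sugar starvation stood lower. Over the 12 arrays, the list of heat shock proteins and factors rose relative to other genes with a median log2 change of 1.34 (camera adjusted p = 1.31e-08). Photoprotection and photosystem repair (median 0.24, adjusted p = 0.000127), the Calvin-Benson cycle (0.16, 0.00218), flavonoid and anthocyanin synthesis (0.29, 4.34e-05), abscisic acid, cold and drought genes (0.48, 3.59e-05), jasmonate and wounding genes (0.30, 0.000603) and shade and low-light growth genes (0.37, 0.0418) also rose as lists. Sugar starvation and dark-induced genes fell (median -1.13, 0.000338). With an estimated correlation between genes these 8 calls were lost, at an adjusted p = 0.514 to 0.517 with an estimated correlation. Among the members, HSP70-4, a cytosolic chaperone, had a log2 difference of 4.53 (SE 2.03), F3H, an enzyme of flavonoid synthesis, 2.15, and TPS8, a trehalose phosphate synthase homologue induced by sugar starvation, -2.35. None of the members of these 8 lists passed over all genes or adjusted over the list alone. Limma called 0 of 28403 probe sets, with 1751 at an unadjusted p under 0.05 and a smallest adjusted p of 0.713, and 0 were called with a mean-dependent prior, a robust prior or array weights. Without WT_HL_2, 1 probe set was called, and the abscisic acid list lost its call (adjusted p = 0.247). The Calvin-Benson call was lost without WT_LL_2 (0.251) and the shade call without WT_LL_1, WT_LL_3, WT_HL_1 or WT_HL_3 (0.13, 0.186, 0.0949 and 0.105).

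The remaining lists were not called in WT over the 12 arrays. ROS and stress regulators had a median of 0.21 (camera adjusted p = 0.0884), with ZAT10, a zinc finger repressor, at 1.41 (SE 0.31) as the only member that passed adjusted over the list alone (0.0159). HY5 and photoreceptor signalling had 0.44 (0.0884), root markers -0.07 (0.0763), nuclear-encoded photosystem subunits -0.08 and the light-harvesting antenna -0.12 (0.242 each). Cytosolic ribosomal proteins (0.05), translation factors and TOR signalling (0.03), nuclear-encoded plastid ribosomal proteins (-0.10) and salicylate and defence genes (-0.11) also had 0.242. The other lists were AP2/ERF factors (-0.10, 0.907), tetrapyrrole synthesis (0.03, 0.543; its mean was -0.01), antioxidant enzymes (0.05, 0.297), the circadian clock (0.08, 0.526), the SAP family (0.11, 0.356), calmodulins (-0.02, 0.547; its mean was 0.09), flower and pollen markers (-0.06, 0.333), guard cell markers (-0.01, 0.648; its mean was 0.06) and mitochondria-encoded genes (-0.02, 0.49).

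In the arrays labelled WT, the genes with the largest increases in the 9 arrays encoded chaperones and their regulators. HSP90.1 rose by 6.54 in log2 (SE 0.25, adjusted p = 1.35e-06, n = 2 HL and 3 LL arrays). HSP17.8, a small heat shock protein (AT1G07400, chromosome 1, 2274943 to 2275758), rose by 6.24, HSP70-4 (AT3G12580, chromosome 3, 3991261 to 3993792) by 5.92, the co-chaperone ROF2 (AT5G48570, chromosome 5, 19690542 to 19693845) by 5.81, the heat shock factor HSFA2 (AT2G26150, chromosome 2, 11135682 to 11137396) by 4.89 and the disaggregase HSP101 by 4.60. GPT2, the glucose 6-phosphate/phosphate translocator of the plastid envelope (AT1G61800, chromosome 1, 22824440 to 22826774), rose by 4.73 (SE 0.18, adjusted p = 1.35e-06). AT5G12110, annotated as a subunit of elongation factor 1-beta, rose by 4.8, the MYB-related factor ASG4 by 4.67 and the prenyltransferase cPT4 by 4.53. BT2, a sugar- and nitrogen-responsive BTB domain protein (AT3G48360, chromosome 3, 17908192 to 17910525), fell most, with a change of -5.79 (SE 0.28, adjusted p = 2.9e-06). AT1G80440, a kelch repeat F-box protein gene, changed by -3.99, the B-box factor BBX14 by -3.82 and TPS8 by -3.46. The decreases of AT3G15630, AT3G15450, AT3G62550, AT2G20670, AT5G22920 and AT5G44260 lay between -3.89 and -3.45. Limma called 2594 probe sets, 1418 higher and 1176 lower in HL, of which 748 and 496 changed by at least 1 in log2. The count was 1231 without WT_HL_1 and 1261 without WT_HL_3, each of which left 1 HL array, whose spread is taken from the other groups.

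Grouped by function, the 9 arrays gave 23 of 27 heat shock genes up in WT, over all genes and adjusted over the list alone (camera adjusted p = 1.75e-29; adjusted p = 0.101 with an estimated correlation). FES1A, a nucleotide exchange factor of HSP70, rose by 3.2. Of 16 sugar starvation genes, 14 fell over all genes, and 14 fell and 1 rose adjusted over the list alone (median -1.96, 4.5e-16; adjusted p = 0.145 with an estimated correlation), among them the trehalose phosphate synthase homologue TPS11 at -3.0 and KMD4, a kelch repeat F-box protein, at -2.49. Flavonoid synthesis rose (8 of 23 members up, 9 adjusted over the list alone, median 0.47, 3.32e-06; adjusted p = 0.145 with an estimated correlation), with F3H at 2.93, CHS, the entry enzyme chalcone synthase, at 1.76 and PAL1 at 0.84. Jasmonate and wounding genes rose (7 of 22, 10 adjusted over the list alone, median 0.39, 2.37e-06; adjusted p = 0.288 with an estimated correlation), with the regulator MYC2 at 1.54 and the biosynthetic enzyme OPR3 at 1.19. Photoprotection and repair genes rose (6 of 20, 9 up and 2 down adjusted over the list alone, median 0.31, 3.06e-05; adjusted p = 0.288 with an estimated correlation), with the thylakoid proteases FTSH8 at 1.02 and FTSH1 at 0.79 and zeaxanthin epoxidase (ZEP) at 0.90. ROS and stress regulators rose (7 up and 1 down of 23, 8 and 1 adjusted over the list alone, median 0.42, 0.000758; adjusted p = 0.145 with an estimated correlation), with the NAC factors ANAC032 at 3.31 and ANAC102 at 1.74, while MYB51, a regulator of indole glucosinolates, changed by -0.98. Calvin-Benson genes rose (7 of 21, 8 adjusted over the list alone, median 0.23, 0.000533; adjusted p = 0.552 with an estimated correlation), with the aldolase FBA1 at 1.39 and the Rubisco small subunit RBCS2B at 1.54.

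Genes of light signalling and shade growth were also called as lists in WT over the 9 arrays. HY5 and photoreceptor signalling rose (9 up and 3 down of 17, 9 and 6 adjusted over the list alone, median 0.65, camera adjusted p = 0.00564; adjusted p = 0.446 with an estimated correlation), led by the bZIP factors HYH at 3.23 and HY5 at 2.49 and phytochrome B (PHYB) at 2.18. Shade and low-light growth genes rose as a list (5 up and 2 down of 15, 8 and 3 adjusted over the list alone, median 0.45, 0.0272; adjusted p = 0.507 with an estimated correlation), in which PIL1, ATHB2 and the auxin synthesis gene YUC9 rose by 2.57, 1.84 and 2.11 and the growth-promoting bHLH factor PIF4 changed by -1.80. The shade call was lost without WT_LL_1, WT_LL_3 or WT_HL_3 (0.0519, 0.0679 and 0.0523). Antioxidant enzymes (5 of 32 up by either adjustment, median 0.11, 0.0445; adjusted p = 0.686 with an estimated correlation) included catalase CAT2 at 2.29, ascorbate peroxidase APX1 at 1.70 and glutathione reductase GR1 at 1.13, and cytosolic ribosomal proteins had 0 of 31 members called by either adjustment (median 0.12, 0.0445; adjusted p = 0.686 with an estimated correlation). The antioxidant call was lost without WT_LL_2 or WT_HL_3 (0.218 and 0.0523), and the ribosomal call without WT_LL_2, WT_LL_3 or WT_HL_3 (0.0912, 0.0579 and 0.263).

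Members of lists that were not called in the 9 WT arrays also changed. In the circadian clock list (6 up and 5 down of 21, 8 and 6 adjusted over the list alone, median 0.08, camera adjusted p = 0.163) the morning genes CCA1 and PRR9 rose by 3.98 and 4.40. S6K1, the ribosomal protein S6 kinase of TOR signalling, rose by 1.70 and S6K2 by 0.92 among 18 translation and TOR genes (median 0.07, 0.163). SAP3 itself rose by 1.37 (SE 0.17, adjusted p = 0.000639) and SAP6 by 1.2, while SAP1 changed by -1.59 and SAP4 by -1.37, so that 2 of 14 SAP family genes rose and 2 fell (median 0.09, 0.501). Among abscisic acid genes (4 up and 2 down of 24, median 0.22, 0.112) ATHB12 rose by 1.71 and the dehydrin gene LTI30 changed by -1.33. For AP2/ERF factors (3 up and 1 down of 20, 0.877) the median was -0.09, the mean -0.02 and the test direction up, with ERF4 at 1 and ERF2 at -1.53. The protochlorophyllide reductase genes PORB and PORA changed by -1.1 and -0.76 within tetrapyrrole synthesis (0 up and 3 down of 20, median 0.04, 0.881), and LHCB4.2 by -0.67 within the antenna (0 and 2 of 20, median -0.15, 0.152). Salicylate and defence (1 and 2 of 20, median -0.06, 0.501) included WRKY70 at -1.51 and PR5 at 0.62, and calmodulins (2 and 0 of 20, 0.161) included CML9 at 1.5. The photosystem subunits (median -0.05, 0.358), plastid ribosomal proteins (-0.09, 0.474), root markers (-0.10, 0.141) and flower markers (-0.09, 0.612) had 0 members called. Among guard cell markers (median 0.02, 0.501) the potassium channel KAT1 rose by 1.91 and the kinase BLUS1 changed by -1.00. Mitochondria-encoded genes had 1 of 57 called (median 0.02, 0.589).

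In the arrays labelled sap3, sugar starvation genes stood lower and jasmonate genes higher in HL than in LL over the 12 arrays. The sugar starvation list fell with a median of -0.87 (camera adjusted p = 0.00361), and the jasmonate and wounding list rose with a median of 0.31 (0.000179). Mitochondria-encoded genes rose with a median of 0.08 (0.00361). All 3 had an adjusted p = 0.831 with an estimated correlation, and none of their members passed over all genes or adjusted over the list alone. AKINBETA1, a subunit of the SnRK1 energy-sensing kinase, had a difference of -1.07 and the asparagine synthetase ASN1 -0.71, and JAZ1, a repressor of jasmonate responses, had 0.74. Heat shock genes had a median of 0.22 (0.525) and were not called, nor were the other lists, with adjusted p-values of 0.0662 (flavonoid synthesis) to 0.891. Limma called 0 probe sets, with 891 at an unadjusted p under 0.05 and a smallest adjusted p of 0.354, and 0 with a mean-dependent prior, a robust prior or array weights. The sugar starvation call was lost without sap3_LL_1, sap3_LL_3, sap3_HL_1 or sap3_HL_2 (0.0543, 0.162, 0.665 and 0.109), the jasmonate call without sap3_HL_1 or sap3_LL_3 (0.511 and 0.0557) and the mitochondrial call without sap3_LL_1 or sap3_HL_3 (0.0543 and 0.579). Of 26 lists, 10 were called without sap3_LL_2, 5 without sap3_HL_2 or sap3_HL_3, and 1 without sap3_LL_1 or sap3_HL_1.

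Chaperone genes again had the largest increases in the arrays labelled sap3 when the 3 arrays were left out. HSP90.1 rose by 6.62 in log2 (SE 0.27, adjusted p = 2.36e-06, n = 2 HL and 2 LL arrays), HSP70-4 by 6.36, HSP17.8 by 6.34, ROF2 by 5.96, HSFA2 by 5.34 and the DnaJ-type co-chaperone gene AT1G71000 by 5.04. AT5G12110 rose by 5.02, ASG4 by 4.78, CP1, a calcium-binding protein, by 4.77 and GPT2 by 4.71. BT2 changed by -5.84, AT3G15450 by -4.46, AT1G80440 by -4.22, BBX14 by -4.04, TPS8 by -3.50 and TPS11 by -3.49. The decreases of AT3G62550, AT2G20670, AT5G44260 and AT1G02610 lay between -3.96 and -3.58. SAP3 rose by 1.04 (SE 0.19, adjusted p = 0.00677). Limma called 2150 probe sets, 1163 higher and 987 lower in HL, of which 723 and 521 changed by at least 1 in log2. The count was 1211 without sap3_HL_1, 1300 without sap3_LL_3 and 1201 when only the sap3 arrays entered the fit.

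Over the 9 arrays, 13 lists were called in the arrays labelled sap3, 0 of them with an estimated correlation. In WT and in sap3 between light levels, fry called a number of lists similar to that of camera. Heat shock genes rose (21 of 27, 22 adjusted over the list alone, median 2.05, camera adjusted p = 1e-28; adjusted p = 0.107 with an estimated correlation) and sugar starvation genes fell (14 of 16, 15 adjusted over the list alone, median -2.56, 2.36e-18; adjusted p = 0.199 with an estimated correlation). Jasmonate genes rose (8 of 22, 13 adjusted over the list alone, median 0.64, 9.82e-09; adjusted p = 0.29 with an estimated correlation), with MYC2 at 1.85 and JAZ9 at 2.09, as did flavonoid synthesis (6 of 23, 7 adjusted over the list alone, median 0.54, 0.000317; adjusted p = 0.29 with an estimated correlation), with F3H at 2.47. Abscisic acid genes rose (6 up and 1 down of 24, 7 and 1 adjusted over the list alone, median 0.48, 0.00068; adjusted p = 0.483 with an estimated correlation), with ATHB12 at 1.34, RD22 at 1.07 and LTI30 at -1.3. Photoprotection (4 of 20, 6 up and 1 down adjusted over the list alone, median 0.26, 0.006) and HY5 signalling (9 up and 3 down of 17, 9 and 5 adjusted over the list alone, median 0.67, 0.00805) rose, both at an adjusted p = 0.483 with an estimated correlation, with the quenching protein gene PSBS at 0.79 and HYH at 2.84. The circadian clock list (6 of 21 up, 6 up and 2 down adjusted over the list alone, median 0.06, 0.00862; adjusted p = 0.354 with an estimated correlation) and ROS and stress regulators (5 up and 1 down of 23, 7 and 2 adjusted over the list alone, median 0.05, mean 0.43, 0.0303; adjusted p = 0.372 with an estimated correlation) were called up, with CCA1 at 3.29 and ANAC032 at 3.68. Without sap3_LL_1 the photoprotection call was lost (0.0667), without sap3_HL_2 the HY5 and clock calls (0.0829 and 0.0873), without sap3_LL_3 the clock and ROS calls (0.0658 and 0.135), and without sap3_HL_1 the ROS call (0.0658).

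Photosynthesis genes were called down as lists in the arrays labelled sap3 over the 9 arrays. The antenna list fell (0 up and 4 down of 20 by either adjustment, median -0.35, camera adjusted p = 0.0017; adjusted p = 0.588 with an estimated correlation), with LHCB1.2 at -1.2 and LHCB4.2 at -0.94. Photosystem subunits fell (0 and 2 of 26, median -0.25, 0.0017; adjusted p = 0.618 with an estimated correlation), with PSAD2 at -1.06 and the plastocyanin gene PETE1 at -0.70. Tetrapyrrole synthesis fell (0 and 3 of 20, 1 and 5 adjusted over the list alone, median -0.23, 0.0238; adjusted p = 0.618 with an estimated correlation), with PORB at -1.31 and CHLM at -1.04, and plastid ribosomal proteins fell without a called member (median -0.26, 0.00206; adjusted p = 0.654 with an estimated correlation). Without sap3_HL_2, 7 lists were called and the antenna, photosystem, tetrapyrrole and plastid ribosomal calls were lost (0.0957, 0.225, 0.158 and 0.461); without sap3_LL_3 the antenna and tetrapyrrole calls were lost (0.0658 and 0.267). Lists not called were AP2/ERF factors (median -0.28, 0.385; ERF2 at -1.80), the Calvin-Benson cycle (0.11, 0.105; FBA1 at 0.94), antioxidant enzymes (median -0.02, mean 0.24, 0.212; 6 of 32 up, with APX1 at 2.13 and CAT2 at 2.15), shade genes (0.36, 0.0843), the SAP family (0.19, 0.288; SAP1 at -1.53), translation and TOR genes (0, 0.385; S6K1 at 1.75), calmodulins (0.03, 0.409), cytosolic ribosomal proteins (0.04, 0.617), salicylate genes (-0.06, 0.971), mitochondria-encoded genes (0.03, 0.483), root markers (-0.06, 0.483), flower markers (-0.01, 0.973) and guard cell markers (-0.07, mean 0.09, 0.483; KAT1 at 1.6).

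Over annotated processes, genes for protein folding and stress were over-represented among the increases called without the 3 arrays. In WT, 90 of 249 loci annotated to the response to heat rose against 15.1 by chance, and in sap3 80 against 12.9 (Fisher's exact test, adjusted p = 2.26e-43 and 5.08e-39). Endoplasmic reticulum stress had 57 of 169 in WT and 54 in sap3 (10.2 and 8.8 by chance, adjusted p = 1.31e-25 and 3.84e-26), and the response to karrikin 40 of 127 and 35 (7.7 and 6.6 by chance). Among the decreases, the response to fructose had 27 of 146 in WT and 28 in sap3 (6.8 and 5.8 by chance, adjusted p = 5.25e-07 and 3.1e-09), and the response to brassinosteroid, a growth hormone, 16 of 77 in each (3.6 and 3.1 by chance, adjusted p = 7.83e-05 and 1.35e-05).

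The light responses of the arrays labelled WT and sap3 were compared probe set by probe set, with no shared arrays. Over the 12 arrays the log2 changes had a Pearson correlation of 0.519 across probe sets, which are not independent replicates, and a slope of 0.358. Without the 3 arrays the correlation was 0.799 and the slope 0.821. Of the probe sets called in the 9 arrays, 952 rose in both genotypes against 58.1 for independent lists, 718 fell in both against 40.9, and 1 went opposite ways. The 9 arrays were kept by their light level, so this agreement is partly fixed by that choice. Both lists also come from 1 fit with a shared spread for each probe set. The numbers for independent lists are thus only a rough reference. The 12-array correlation was 0.684 without sap3_LL_2 and 0.689 without sap3_HL_3, and 0.238 to 0.297 without sap3_HL_1, sap3_LL_1, sap3_LL_3 or sap3_HL_2.

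The pools, which have 1 array per group and therefore no test, showed the same leading genes in the step from LL to HL. In the pools labelled WT the log2 difference was 6.83 for HSP90.1, 6.78 for HSP70-4, 6.65 for HSP17.8, 6.12 for ROF2, 5.56 for HSFA2, 5.36 for AT1G71000, 5.31 for AT5G12110 and 5.12 for the small heat shock protein gene AT2G29500. RD28, an aquaporin, had 5.46 and TIN1 4.92. The most negative differences were -6.41 for BT2, -5.48 for AT5G22920, -5.37 for AT3G15450, -5.07 for AT1G02610, -4.74 for AT2G20670 and -4.71 for TPS8. In the pools labelled cml49 the differences were 6.84 for HSP90.1, 6.62 for HSP17.8, 6.34 for HSP70-4, 5.40 for ROF2, 4.69 for cPT4, 4.66 for CP1, 4.55 for GPT2 and 4.54 for GBSS1, a granule-bound starch synthase, against -5.28 for BT2, -4.31 for AT1G02610 and, among others, -3.88 for BBX14, -3.85 for TPS11, -3.83 for TPS8 and -3.59 for the protein kinase gene CIPK21. An absolute difference of at least 1 was met by 2200 probe sets in the pools labelled WT (1247 higher in HL) and 1806 in those labelled cml49 (981 higher), and 649 were higher in both pairs against 43.1 for independent lists. Of the probe sets called without the 3 arrays in WT or sap3, 95.7% to 97.5% had the same sign in either pair of pools. The other arrays were kept by a light score whose probe sets were chosen on these same pools. Their agreement with the pools, in sign and in the leading genes, is therefore partly fixed by that choice and is not independent evidence.

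Gene lists in the pools were set against 10000 random lists of matched expression, as a description of these arrays. Heat shock genes had a median of 2.25 in the pools labelled WT (21 of 27 higher by at least 1) and 2.07 in those labelled cml49 (20 of 27), both at percentile 100, and sugar starvation genes had -2.64 (15 of 16 lower) and -2.17 (12 of 16), both at percentile 0. ROS and stress regulators had 0.63 and 0.77, shade genes 1.00 and 0.66 and jasmonate genes 0.45 and 0.44, each at percentile 100. Flavonoid synthesis had 0.63 and 0.35 and HY5 signalling 0.50 and 0.44, at or above percentile 99.97.

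Between genotypes in LL, regulators of stress responses stood higher in the arrays labelled sap3 than in those labelled WT. Over the 12 arrays, ROS and stress regulators rose as a list (median 0.37, camera adjusted p = 5.45e-08; adjusted p = 0.228 with an estimated correlation), with 0 of 23 members passing over all genes and 4 adjusted over the list alone. These were ZAT10 at 1.63 (SE 0.31), the zinc finger genes SZF2 at 0.94 (SE 0.15) and SZF1 at 0.67, and WRKY33, a defence regulator, at 1.13. AP2/ERF factors (median 0.15, 0.025) and calmodulins (0.19, 0.00107) were called up, both at an adjusted p = 0.228 with an estimated correlation, with ERF6 at 1.04 and the touch-induced calmodulin-like genes CML12 at 1.74 and CML24 at 1.13, none of which passed. Heat shock genes (median 1.18, 5.45e-08; adjusted p = 0.724 with an estimated correlation) and flavonoid genes (0.14, 0.0351; adjusted p = 0.737 with an estimated correlation) were also called up. Called down were plastid ribosomal proteins (-0.23, 2.1e-06; adjusted p = 0.737 with an estimated correlation), photosystem subunits (-0.12, 0.0136; adjusted p = 0.772 with an estimated correlation), the antenna (-0.12, 0.0304; adjusted p = 0.745 with an estimated correlation), cytosolic ribosomal proteins (-0.08, 0.025) and mitochondria-encoded genes (-0.11, 0.0124), the last 2 at an adjusted p = 0.737 with an estimated correlation. Limma called 0 probe sets, with 1283 at an unadjusted p under 0.05 and a smallest adjusted p of 0.562, and 0 with a mean-dependent prior, a robust prior or array weights. Root, flower and guard cell markers had medians of -0.05, 0.05 and 0 and were not called (0.986, 0.993 and 0.736). SAP3 differed by 0.14 (SE 0.79, adjusted p = 0.993).

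Several of these LL calls rested on single arrays, among them sap3_LL_2, whose light score of 0.95 lay near the HL pools. Without sap3_LL_2 the heat shock, plastid ribosomal, cytosolic ribosomal and flavonoid calls were lost (camera adjusted p = 0.675, 0.436, 0.306 and 0.771), the antenna and photosystem lists changed direction (1 and 0.967), and 4 lists were called in place of 10, while 5 were called without WT_LL_3. The antenna, photosystem, cytosolic ribosomal and mitochondrial calls were lost without WT_LL_1 (0.108, 0.102, 0.11 and 0.0636), the first 3 also without WT_LL_3 (0.238, 0.369 and 0.0758), and the mitochondrial call without sap3_LL_1 or WT_LL_2 (0.0862 and 0.321). The AP2/ERF call was lost without sap3_LL_1, sap3_LL_3 or WT_LL_3 (0.248, 0.0738 and 0.0758) and the flavonoid call without WT_LL_2, WT_LL_3 or sap3_LL_3 (0.0951, 0.135 and 0.114). The ROS and calmodulin calls held without each array.

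ROS and stress regulators were again called up in LL over the 9 arrays in the arrays labelled sap3 (median 0.24, camera adjusted p = 2.96e-07; adjusted p = 0.0868 with an estimated correlation), with 0 of 23 members over all genes and 8 adjusted over the list alone. ZAT10 was higher by 1.45 (SE 0.22, adjusted p = 0.321 over all genes and 0.0013 over the list alone), and WRKY53, MYB51 and SZF2 had differences of 1.13, 0.73 and 0.81. AP2/ERF factors (median 0.21, 0.000579; adjusted p = 0.0868 with an estimated correlation; 3 members adjusted over the list alone) included ERF6 at 1.42, DREB26 at 1.12 and the cold response factor CBF2 at 0.98, and calmodulins (0.20, 0.00232; adjusted p = 0.125 with an estimated correlation; 2 members adjusted over the list alone) CML12 at 1.52 and CML24 at 1.02. Sugar starvation genes (0.30, 0.000648) were called up and mitochondria-encoded genes (-0.08, 0.00232) down, both at an adjusted p = 0.934 with an estimated correlation. The sugar starvation call was lost without sap3_LL_3 (0.263) and the mitochondrial call without sap3_LL_1 or WT_LL_2 (0.0869 and 0.149). Heat shock genes had a median of 0.11 (0.343), the antenna 0.05 (0.94) and plastid ribosomal proteins -0.06 (0.343). SAP3 was lower by 0.81 (log2 difference -0.81, SE 0.17), which passed adjusted over the SAP list alone (0.01) but not over all genes (0.475). Limma called 0 probe sets, with 1706 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0545, 5 with a mean-dependent prior and 0 with a robust prior or array weights. Those 5 were MRD1 (log2 difference -1.85, adjusted p = 0.0159), AT5G11330 (-1.13, 0.0159), ZAT10 (1.45, 0.0337), the calcium-dependent protein kinase CPK28 (0.9, 0.0337) and HIR2 (1.15, 0.0444), named after their values were seen. MRD1 alone was called without sap3_HL_1 or sap3_HL_2 (0.03 each), and AT3G01345 without WT_LL_2 (-3.38, 0.00537).

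In HL, the arrays labelled sap3 and WT differed over the 12 arrays by higher stress regulators and lower abscisic acid genes as lists. ROS and stress regulators were called up (median 0.32, camera adjusted p = 1.06e-05; adjusted p = 0.327 with an estimated correlation), with WRKY33 at 1.08, SZF1 at 0.63 and the kinase MPK3 at 0.44. Abscisic acid, cold and drought genes were called down (-0.28, 2.09e-05; adjusted p = 0.449 with an estimated correlation), with the dehydrin RAB18 at -1.41, ATHB7 at -1.01 and KIN1 at -0.84. Salicylate and defence genes (0.14, 0.012) and calmodulins (0.17, 0.012) were called up, both at an adjusted p = 0.327 with an estimated correlation, with the salicylate regulator CBP60G at 0.68 and CML12 at 1.01. Jasmonate genes were called up (0.16, 0.0356), and cytosolic ribosomal proteins (-0.10, 0.0165) and plastid ribosomal proteins (-0.10, 0.0101) down, all at an adjusted p = 0.82 with an estimated correlation. None of the members named passed over all genes or adjusted over the list alone. Limma called 0 probe sets, with 812 at an unadjusted p under 0.05 and a smallest adjusted p of 0.605, and 0 with a mean-dependent prior, a robust prior or array weights, while 1 was called without WT_HL_2. Root and flower markers had medians of 0.04 and 0.06 and were not called (0.34 and 0.297), and 1 guard cell marker was lower adjusted over the list alone (list 0.34). SAP3 had a difference of -0.83 (adjusted p = 1).

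All of these HL calls depended on single arrays. Without WT_HL_2 the ROS, salicylate, calmodulin, jasmonate and abscisic acid calls were lost (camera adjusted p = 0.0612, 0.0612, 0.263, 0.973 and 0.246), and the last also without sap3_HL_3 (0.328). Without sap3_HL_2 the calmodulin, jasmonate and cytosolic ribosomal calls were lost (0.326, 0.394 and 0.671), plastid ribosomal proteins changed direction (0.598), and 4 lists were called in place of 7. Jasmonate genes changed direction without sap3_HL_1 (0.787), where the salicylate call was lost (0.0653). The cytosolic ribosomal call was lost without WT_HL_1 or WT_HL_3 (0.184 and 0.628), and the salicylate and plastid ribosomal calls without WT_HL_3 (0.0636 each). Without sap3_HL_3, 11 lists were called.

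In the 9 arrays, plastid and cytosolic ribosomal proteins and photosynthesis genes were called lower in HL in the arrays labelled sap3, and ROS regulators and jasmonate genes higher. The medians were -0.23 for plastid ribosomal proteins (camera adjusted p = 2.48e-07), -0.21 for cytosolic ribosomal proteins (2.58e-05), -0.21 for photosystem subunits (8.28e-05), -0.21 for tetrapyrrole synthesis (0.00029), -0.17 for the antenna (0.00183), -0.14 for the Calvin-Benson cycle (0.00234) and -0.07 for mitochondria-encoded genes (0.00597). Called up were ROS regulators (0.29, 1.68e-05; adjusted p = 0.209 with an estimated correlation), jasmonate genes (0.34, 2.58e-05), calmodulins (0.19, 0.0278) and salicylate genes (0.13, 0.0337). Apart from ROS regulators, these lists had an adjusted p = 0.562 with an estimated correlation. Examples were PRPL12C at -0.54, RPL23AB at -0.58, LHCB1.2 at -0.57, MYB51 at 0.66 and JAZ10 at 0.52, and no list member passed over all genes. Adjusted over the list alone, 1 member passed, SAP3 at -1.14 (SE 0.19, 0.00151 over the SAP list alone and 0.549 over all genes). Abscisic acid genes had a median of 0.11 (0.108), opposite in sign to the 12 arrays. Without sap3_HL_2, the calls of the antenna (0.592), photosystem subunits (0.605), the Calvin-Benson cycle (0.409), tetrapyrrole synthesis (0.166), cytosolic ribosomal (0.424), plastid ribosomal (0.409), mitochondria-encoded (0.619), salicylate (0.0542) and calmodulin genes (0.424) were lost and 4 lists were called. The calmodulin call was lost without WT_HL_1 (0.258), the jasmonate call without sap3_HL_1 (0.0894), the salicylate call without sap3_HL_1 or WT_HL_3 (0.273 and 0.322) and the mitochondrial call without WT_HL_3 (0.336).

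A single probe set was called between genotypes in HL over the 9 arrays. AT3G60950 (chromosome 3, 22524475 to 22530306), annotated as a C2 domain and endonuclease/exonuclease/phosphatase family protein, was lower in the arrays labelled sap3, with a log2 difference of -1.97 (SE 0.15, limma adjusted p = 0.00464). Its signal was 4.06 ± 0.13 in WT_HL and 2.08 ± 0.16 in sap3_HL (SD, n = 2 each). The adjusted p was 0.00339 to 0.0415 in the settings that called it. The call was lost without WT_HL_1, WT_HL_3 or sap3_HL_2, where 0 probe sets were called, and in a fit of the 2 HL groups alone (0.131). Its signal is low, and 0 were called without dim probe sets or with a replicate block. Without WT_LL_2, AT3G01345 was called beside it (-5.16, 0.000145).

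**Figure D2:**
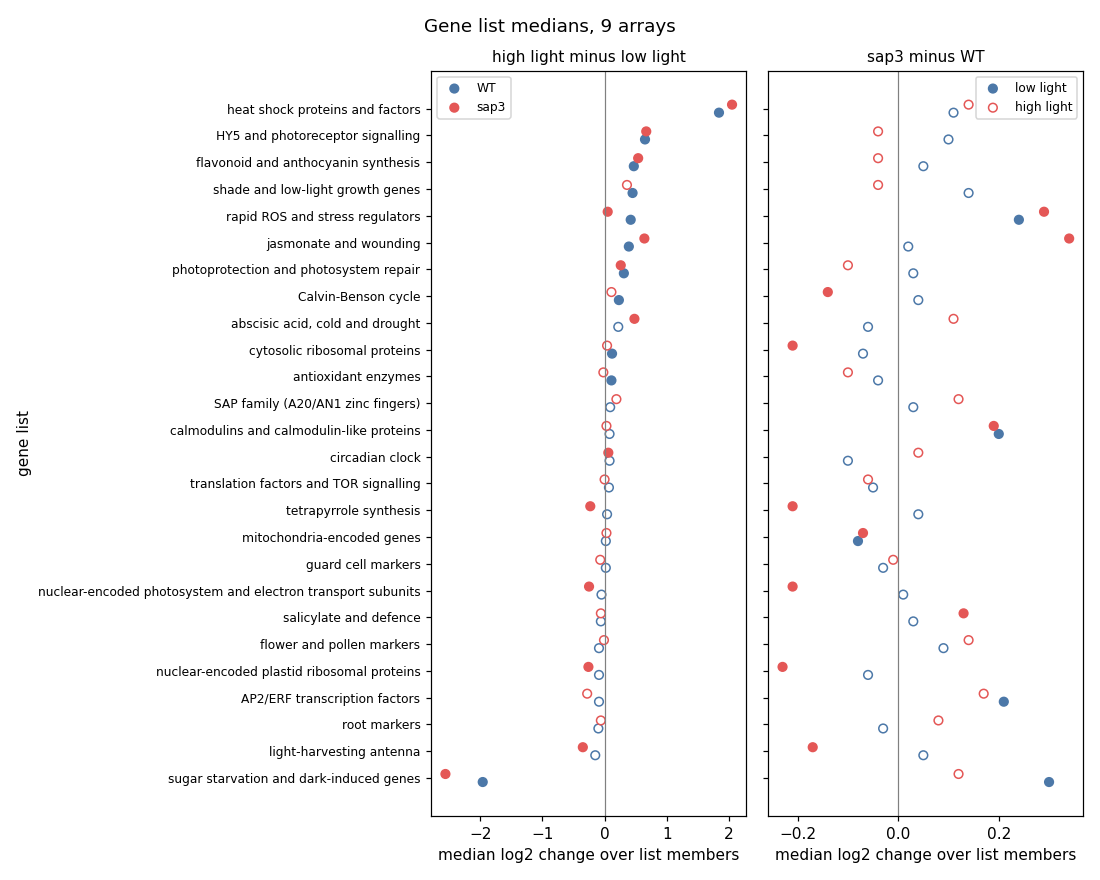
Median log2 difference of each gene list over 9 arrays, without the 3 arrays whose light score opposes their label, for high minus low light (left, blue WT and red sap3 as labelled) and for sap3 minus WT (right, blue low light and red high light), with filled points where the camera adjusted p was under 0.05. Heat shock genes lie at 1.84 and 2.05 and sugar starvation genes at -1.96 and -2.56 on the left, while on the right all medians lie within 0.34 of 0.

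Whether the light response differed between the arrays labelled sap3 and WT was tested as the interaction. Over the 12 arrays, the heat shock list had a smaller light response in the arrays labelled sap3 (median difference -1.22, camera adjusted p = 3.64e-05), with HSFA3 at -1.32, HSP18.2 at -1.22 and HSFB2A at -0.74, and mitochondria-encoded genes a larger one (0.14, 0.00687). Both had an adjusted p = 0.918 with an estimated correlation, and none of the members passed over all genes or adjusted over the list alone. The heat shock call was lost without sap3_LL_2 or sap3_HL_3 (0.795 and 0.22), and over the 9 arrays the median was 0.10, of the opposite sign (0.728). The light scores of both arrays oppose their labels, which lowers the light difference in sap3 as labelled. The mitochondrial call was lost without WT_LL_1, WT_LL_2, WT_HL_2 or sap3_HL_3 (0.0578, 0.144, 0.279 and 0.49). The other 24 lists were not called. Limma called 0 probe sets, with 744 at an unadjusted p under 0.05 and a smallest adjusted p of 0.999, and 0 with a mean-dependent prior, a robust prior or array weights. The probe sets with the smallest p, none of which passed, were ARF22, an auxin response factor gene, at 1.09 (SE 0.20), AT5G33355 at -1.56 (0.31), AT5G38090 at 1.01, AT1G08440, a malate transporter family gene, at -1.65 (0.34) and DOX1, a fatty acid dioxygenase, at -1.58 (0.33).

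Without the 3 arrays, 6 lists were called in the interaction, 5 of them, of photosynthesis and plastid ribosomal genes, with a more negative light response in the arrays labelled sap3. These 5 were tetrapyrrole synthesis (median -0.24, camera adjusted p = 0.00423; chlorophyllide a oxygenase CAO at -0.56, HEMA1 at -0.47), photosystem subunits (-0.22, 0.0101; PSAN at -0.43), plastid ribosomal proteins (-0.18, 0.0101; PRPL11 at -0.43), the Calvin-Benson cycle (-0.21, 0.0213; FBA1 at -0.45) and the antenna (-0.16, 0.0301; LHCB1.2 at -0.75). Abscisic acid genes differed the other way (0.24, 0.0301; RD26 at 0.64). All 6 had an adjusted p = 0.705 with an estimated correlation and no member passed over all genes or adjusted over the list alone. Without WT_LL_2 1 list was called, without WT_HL_3 1, without sap3_LL_3 0 and without sap3_LL_1 10. The tetrapyrrole call was lost without WT_LL_2, sap3_HL_2 or sap3_LL_3 (0.098, 0.0842 and 0.184), and so were the photosystem (0.266, 0.833 and 0.219), plastid ribosomal (0.453, 0.984 and 0.184), Calvin-Benson (0.412, 0.399 and 0.184) and antenna calls (0.266, 0.827 and 0.643). Without WT_HL_3 the photosystem, plastid ribosomal, Calvin-Benson and abscisic acid calls (0.0589 each) and the antenna call (0.077) were lost, and without WT_HL_1 the antenna, Calvin-Benson and abscisic acid calls (0.0703 each). The abscisic acid call was also lost without sap3_HL_1, WT_LL_2 or sap3_LL_3 (0.561, 0.266 and 0.643). Limma called 0 probe sets, with 1192 at an unadjusted p under 0.05, a smallest adjusted p of 0.3, and 0 with a mean-dependent prior, a robust prior or array weights. The smallest p-values, none passing, belonged to AT3G60950 (-1.69, SE 0.21), AT5G11230 (-1.62), AT3G16851 (1.37), the monodehydroascorbate reductase gene MDHAR (1.23) and the purple acid phosphatase PAP8 (-1.27). SAP3 had an interaction of -0.33 (SE 0.25).

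The comparison of cml49 with WT rests on 1 pool each, and CML49 itself was higher in the pools labelled cml49. Single genes are named among the probe sets outside the range of the WT pool and WT replicates. In LL, the pool labelled cml49 had lower values than the pool labelled WT for BHLH100, an iron deficiency-induced bHLH factor (-1.48), PR5, a pathogenesis-related protein (-1.37), the transporter UMAMIT33 (-1.30), the glutathione transferase GSTF2 (-1.2) and the cyclic nucleotide-gated channel CNGC11 (-1.15), and further for AT5G03090 (-1.69), AT4G36850 (-1.54), AT1G53970 (-1.29), AT4G23870 (-1.25) and AT3G06620 (-1.18). Of the 10 most positive differences named by this rule the highest was AT1G08240 at 2.6, several carried identical values in different loci (AT1G20210 and AT2G33650 at 2.11 each), and some belong to probe sets that lie away from the locus of their annotation and are not named. For most of these 10 the pool labelled WT departed more from the mean of the WT replicates, as for AT1G08240 (5.35, and 7.95 in the pool labelled cml49, against 7.2). The lower genes went both ways. The pool labelled WT departed more for PR5 (6.56 and 5.19 against 5.46) and BHLH100 (5.27 and 3.79 against 4.29). The pool labelled cml49 did for CNGC11 (5.84 and 4.69 against 5.76) and AT4G23870 (6.21 and 4.96 against 5.91). Photosystem subunits and the antenna had medians of -0.29 and -0.28 (percentiles 0 and 0.06 of the random lists), salicylate genes -0.30 (0.05), shade genes -0.23 (0.54), sugar starvation genes -0.20 (0.78) and antioxidant enzymes -0.16 (0.78). An absolute difference of at least 1 was met by 370 probe sets, 302 of them outside the range of the WT pool and WT replicates (178 higher, 124 lower). The 302 became 116 without dim probe sets and 192 with the mean of the WT replicates in place of the WT pool. Single WT replicates in LL differed from each other in 335 to 367 probe sets by that size, against 370 between the pools. Each pool combines 3 replicates, so counts between single replicates, here and in HL below, do not measure the spread expected between pools.

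In HL, heat shock and abscisic acid genes had lower values in the pool labelled cml49 than in the pool labelled WT. The heat shock list had a median of -0.36 (percentile 0), with 5 of 27 members lower by at least 1, among them the small heat shock proteins HSP17.6II at -1.59, HSP17.6C at -1.28 and HSP18.2 at -1.1. Abscisic acid genes had -0.36 (percentile 0; RD29B at -1.18), calmodulins -0.40 (0; CML12 at -1.14, CML49 at 0.93), salicylate genes -0.29 (0), antioxidant enzymes -0.13 (0.03), mitochondria-encoded genes 0.12 (99.94) and sugar starvation genes 0.44 (100; DIN10 at 1.1). Outside the WT range, single differences were ST2A, a hydroxyjasmonate sulfotransferase, at 1.72, the transporters ABCG27 and AT3G56200 at 1.28 each, AT1G21245 at 1.19, the RNA helicase STRS2 at 1.16, EDL3 at 1.12, GRP4 at 1.1, AT5G44565 at 1.08, the calmodulin-binding IQD1 at 1.04 and SHM7 at 1.00, and in the other direction the glucosyltransferase UGT73B5 at -1.71, RLP34 at -1.45, AT1G30250 at -1.31, AT2G14247 at -1.30, the expansin EXPA16 at -1.21, the receptor kinase gene AT1G74360 at -1.19 and AT5G46510 at -1.01. Inside that range, which includes WT_HL_2, AT3G01345 differed by 4.1, a gene chosen after its values were seen. By size, 305 probe sets differed, 140 of them outside the WT range (73 higher, 67 lower; 18 without dim probe sets), against 243 between WT_HL_1 and WT_HL_3 and 1723 and 1795 between either of these and WT_HL_2. The pool labelled WT differed from the mean of WT_HL_1 and WT_HL_3 in 275 probe sets and the pool labelled cml49 in 108. HSP90.1 had 10.33 in the pool labelled WT and 9.9 in the pool labelled cml49, against 9.8 and 9.77 in these replicates, and AT2G29500 had 8.58 and 7.61 against 7.46 and 7.5. For most of the single genes outside the WT range, too, the pool labelled WT departed more from these replicates than the pool labelled cml49 did. ST2A had 3.67 and 5.39 against 5.18 and 4.97, RLP34 6.96 and 5.51 against 5.69 and 5.76, and SHM7 7.45 and 8.45 against 8.15 and 8.19. AT1G74360 went the other way (5.47 and 4.28 against 5 and 5.26).

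The light response of the pool pairs differed in 1211 probe sets by at least 1 (553 higher and 658 lower in the pair labelled cml49). The count was 383 without dim probe sets and 594 with the WT replicates, WT_HL_2 left out, in place of the WT pools. Sugar starvation genes had a median difference of 0.94 (percentile 100; 8 of 16 at least 1, among them the branched-chain catabolism gene DIN3 and DIN10 at 1.24 each and AKINBETA1 at 1.23), heat shock genes -0.37 (0.03), abscisic acid genes -0.33 (0), calmodulins -0.32 (0.36) and tetrapyrrole synthesis -0.18 (0.45). Single genes were AT3G01345 at 3.67, AT5G22920 at 2.06, ERD5, a proline dehydrogenase, at 1.92, AT1G56130 at 1.82, SPL3, a squamosa promoter-binding factor, at 1.67, PR5 at 1.65, RD28 at -2.33 and the proline transporter ProT3 at -2.19. In HL the pool labelled cml49 lay nearer WT_HL_1 and WT_HL_3 than the pool labelled WT did for AT5G22920 (4.51 and 2.82, against 4.1 and 4 in the replicates), RD28 (7.59 and 8.88, against 7.3 and 7.56) and ProT3 (5.89 and 7.39, against 5.99 and 5.67). The same difference of differences between WT replicates 1 and 3 gave 1173 probe sets, the only such count without WT_HL_2, and the pairs with replicate 2 gave 2397 and 2620. These counts, too, are of single replicates and not of pools.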

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

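Every test of an explanation in this part was chosen only after the result was seen, as was the alternative with 9 arrays. Lists whose light response differed between the arrays labelled sap3 and WT met the rule of a tested difference between groups. Over the 12 arrays these were heat shock genes, with a smaller increase in sap3 (camera adjusted p = 3.64e-05), and mitochondria-encoded genes (0.00687), neither of which was called with an estimated correlation (0.918) or by fry (0.978). Over the 9 arrays they were tetrapyrrole synthesis (0.00423), photosystem subunits (0.0101), plastid ribosomal proteins (0.0101), the Calvin-Benson cycle (0.0213), the antenna (0.0301) and abscisic acid genes (0.0301), none of them called with an estimated correlation (0.705) or by fry (0.713). The heat shock difference in the 12 arrays had the opposite sign in the 9 arrays (0.728), and was lost without sap3_LL_2 (0.795) or sap3_HL_3 (0.22) alone. The light score opposed the label in both of these arrays (0.95 and 0.03), but in WT only in WT_HL_2 (0.07). This lowers the labelled light difference more in sap3 than in WT. The 12-array heat shock difference therefore cannot be read as one between genotypes. In the interaction the labelled groups called 0 probe sets, a number that all 100 of 100 random draws of the 12 arrays into 4 groups of 3 reach by construction, so these draws say nothing about chance. The highest other draw called 3879, which points to a structure of the samples, and a light response alone is enough for that, since a draw can place the light levels so that their difference becomes an interaction.

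Splits of the arrays into 3 and 3 are too few for a share under 0.05 in the other comparisons, since only 10 exist. The real split called 0 probe sets in WT between light levels and the highest other split 0. In sap3 between light levels the real split called 0 and the highest other split 2217, which points to a structure of the samples other than the labelled light levels. Between genotypes the values were 0 and 0 in LL and 0 and 1 in HL.

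The first pattern weighed is the light state of WT_HL_2, sap3_LL_2 and sap3_HL_3, which was opposite to their labels for HSP90.1 and for the median of 250 probe sets chosen on the pools. Mixed RNA or a failed array is argued against for the bulk of these probe sets. It would place the score between the ends of the scale, and the largest distance from an end was 0.07. The score does not speak for each gene. In WT_HL_2, HSP70-4 had 7.96 and GPT2 4.51, above the WT means in LL (6.23 and 2.95) and below WT_HL_1 (12.12 and 7.57). ROF2, HSP17.8 and HSFA2 had 4.45, 2.57 and 2.17, near their WT means in LL (4.49, 2.63 and 1.95). An exchange of WT_HL_2 with sap3_LL_2 may account for 2 of the arrays, and each carried the level of the other's label at SAP3 (3.94 and 6.98) and at the 2 probe sets called for genotype in an additive fit of the 9 other arrays, MRD1 (-1.81, adjusted p = 0.00094) and AT5G11330 (-1.03, 0.00803), whose score from WT (0) to sap3 (1) was 1.07 and 0.03. MRD1 was, however, also low in the pools labelled WT. Of the 25 probe sets with the smallest p, 23 of which were not called, 12 lay nearer sap3 in WT_HL_2 and 12 in sap3_LL_2. By the SD of the log2 difference over all probe sets, WT_HL_2 was nearest WT_LL_2 (0.335, against 0.356 and 0.391 to sap3_LL_1 and sap3_LL_3). By the same SD, sap3_LL_2 was nearest sap3_HL_2 (0.336, against 0.373 and 0.376 to WT_HL_1 and WT_HL_3). That SD cannot decide the question, since it did not follow genotype in arrays not in doubt. There sap3_LL_1 lay nearer WT_LL_1, WT_LL_2 and WT_LL_3 (0.339, 0.345 and 0.349) than sap3_LL_3 (0.372). SAP3, MRD1 and AT5G11330 thus go with an exchange, but an exchange and separate errors cannot be told apart. For sap3_HL_3, that score was 1.2 and 14 of 25 markers lay nearer sap3, and plants that were not exposed or did not respond and a wrong light label give the same values and cannot be told apart.

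The second pattern is CML49, which was lower in the pools labelled WT (2.77 and 3.30) than in the pools labelled cml49 (3.97 and 4.23) and than in each of the 12 single-replicate arrays. A CML49 probe set outside the disrupted part of the gene could leave the pools labelled cml49 near the replicates. It would not by itself lower the pools labelled WT, the higher of which lay 0.84 below the lowest single-replicate array (SD 0.13 over the 12). That gap is part of the pattern itself and is no test of where the probe set lies. An exchange of the genotype labels of the pools is a candidate explanation: of 27 probe sets that differed by at least 1 in the same direction at both light levels, 23 lay nearer the WT replicates in the pools labelled cml49, among them BHLH100 and AT3G10310, the next locus after CML49 (2.95 and 2.62 in the pools labelled WT, 4.93 and 3.83 in those labelled cml49), but 9 of the 27 are copies with identical values, and with copies counted once 15 of 19 (78.9%) did. Another genotype in the pools labelled WT cannot be told apart from it, since MRD1 was low in them (2.83 and 2.46) while AT5G11330 (7.18 and 7.25) and SAP3 (4.90 and 6.43) lay near the WT replicates. The score of MRD1 and AT5G11330 was 0.5 and 0.56. It is the median of these 2 probe sets, which lay at opposite ends, and marks no intermediate level. The authors' group means, which match averages of 4 arrays to 0.0047 at most, join the pools labelled cml49 to the WT replicates and the pools labelled WT to the sap3 replicates.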

How the results depend on the processing

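The alternative without the 3 arrays whose light score opposes their label, and the alternatives run on those 9 arrays, were chosen only after the result was seen. So was the pool alternative that leaves out WT_HL_2. The others were planned. Unless a reason is given, the cause was not tested.

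Over the 12 arrays, limma called 0 probe sets in all 5 comparisons, with 1751, 891, 1283, 812 and 744 at an unadjusted p under 0.05. The count was also 0 with a mean-dependent prior, a robust prior, array weights, median centring, a new quantile normalisation, 1 probe set per locus, an adjusted p under 0.01 and without dim probe sets. Leaving out each array in turn gave 0 to 1 in WT between light levels and in HL between genotypes, each with 1 only without WT_HL_2, and 0 to 0 in the others. Without the 3 arrays, 2594 were called in WT, 2150 in sap3, 0 in LL between genotypes, 1 in HL and 0 in the interaction; the arrays were left out by their light score, which by construction lowers the spread within light levels.

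Lists called over the 12 arrays numbered 8 in WT, 3 in sap3, 10 in LL, 7 in HL and 2 in the interaction. With an estimated correlation and with fry 0 were called in each of the 5 comparisons. Without the 3 arrays the numbers were 11, 13, 5, 11 and 6, and a new quantile normalisation gave 6 in LL. Leaving out each array gave 7 to 9, 1 to 10, 4 to 12, 4 to 11 and 1 to 6. Without the 3 arrays the antenna changed direction in LL (0.94), as did abscisic acid genes in HL (0.108) and heat shock genes in the interaction (0.728). Without a single array, directions changed for the antenna and photosystem subunits in LL (1 and 0.967, without sap3_LL_2), and in HL for jasmonate genes (0.787, without sap3_HL_1) and plastid ribosomal proteins (0.598, without sap3_HL_2). Leaving out each array, their adjusted p-values ranged from 0.000125 to 1, 1.61e-05 to 0.967, 5.04e-09 to 0.973 and 1.46e-06 to 0.598. The correlation of the light responses, 0.519, was 0.712 without dim probe sets and 0.799 without the 3 arrays, and 0.238 (without sap3_HL_1) to 0.689 (without sap3_HL_3) when each array was left out.

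Over the 9 arrays, an adjusted p under 0.01 called 1350 in WT and 1106 in sap3, as a stricter threshold must, and a fit of the sap3 arrays alone 1201, with fewer arrays to estimate the spread. In LL, where 0 were called, a mean-dependent prior called 5, removal of dim probe sets 2, median centring 1 and 1 probe set per locus 1, among which MRD1 had adjusted p-values of 0.0159 to 0.0375. In HL, 0 were called without dim probe sets. Leaving out each array gave 1231 (without WT_HL_1) to 2607 in WT, 1211 (without sap3_HL_1) to 2029 in sap3, 0 to 1 in LL, 0 to 2 in HL and 0 to 0 in the interaction. Where this left 1 array in a group, its spread was assumed to be that of the other groups. Lists called over the 9 arrays numbered 0 in all 5 comparisons with an estimated correlation. With fry they numbered 2 in LL, 0 in HL and 0 in the interaction, while in the 2 light comparisons fry called a number similar to that of camera. Without dim probe sets 10 lists were called in the interaction. Leaving out each array gave 8 to 13, 7 to 14, 5 to 6, 4 to 13 and 0 to 10 lists. The correlation of 0.799 was 0.9 without dim probe sets and 0.731 to 0.786 with each array left out.

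A replicate block, which pairs arrays of the same number, called 0 probe sets in each comparison over the 12 arrays, and 7, 3, 11, 8 and 3 lists. Over the 9 arrays the block called 1973, 1686, 0, 0 and 0 probe sets, so that the HL call of AT3G60950 was lost. The block called 9 lists in LL and 1 in the interaction, where the antenna (0.87), photosystem subunits (0.322), the Calvin-Benson cycle (0.562) and plastid ribosomal proteins (0.0646) changed direction. Whether the numbers pair the arrays is not settled. Correlations of the deviations of same-numbered arrays ranged from -0.48 to 0.53 over the 12 arrays, where the 3 arrays with an opposing light score enter them. Over the 9 arrays they ranged from -0.04 to 0.07, with no pair of replicate 2 left.

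In the pools, a size of at least 1.5 gave 916 and 648 probe sets between light levels in WT and cml49, 89 and 24 outside the WT range between genotypes in LL and HL (302 and 140 at a size of 1) and 241 in the difference of the light responses, and a size of log2(1.5) gave 5608, 5276, 1878, 1025 and 5283, as a change of size must. Without dim probe sets the last 3, counted alike, were 116, 18 and 383. With the mean of the WT replicates in place of the WT pool 192 differed in LL, and with the 2 WT_HL replicates other than WT_HL_2 the difference of the light responses had 594. The planned use of the workbook signals in place of the deposited table was not run, since their columns could not be matched to the labels with certainty.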

Other observations

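Genes of this part were chosen after their values were seen. So were all tests it reports, apart from the planned limma and list tests over all single-replicate arrays. In the 9 arrays, genes of protein folding in the endoplasmic reticulum rose with light in both genotypes as labelled. The chaperone BIP1 rose by 2 in WT and 1.89 in sap3 (limma adjusted p = 0.000127 and 0.000409), BIP2 by 1.67 and 1.81, the lectin chaperone CNX1 by 1.71 and 1.67 and SDF2 by 1.14 and 1.32. BZIP60, a transcription factor of the unfolded protein response, rose by 1 in WT (0.0116) and did not pass in sap3 (0.76, 0.0721). Genes of sulfate assimilation rose, with the adenosine phosphosulfate reductases APR1 at 2.52 and 2.96, APR2 at 3.8 and 3.6 and APR3 at 3.75 and 4.64. Genes of glucosinolate synthesis included CYP79B2 at 0.98 and 1.82 and the regulator MYB29 at 0.89 and 1.16, and GBSS1, which makes amylose, rose by 4.32 and 4.1. The annotated process of inositol hexakisphosphate synthesis had 43 of 64 loci up in WT and 30 in sap3 against 3.9 and 3.3 by chance, and sulfate assimilation 8 and 7 of 15 against 0.9 and 0.8.

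The third pattern is the higher level of ROS and stress regulators, such as ZAT10, SZF2 and WRKY33, in the arrays labelled sap3 in LL. A single array is argued against as the source, since the list was called without either remaining sap3 array in LL, with a largest adjusted p of 0.00742. A brief exposure of these plants to brighter light cannot be told apart, since the mean of the heat shock genes shifted by 0.1 (SD 0.06 over the WT arrays in LL) where the same share of their light response (0.76) would need 1.93, but that equal share is an assumption. The loss of SAP3 may raise these regulators, and so could any difference in handling between the genotypes, which the design does not separate from it. The list was not called with an estimated correlation in either set of arrays (0.228 for 12 and 0.0868 for 9), and no member passed over all genes with limma's default prior, while ZAT10 did in the 9 arrays with a mean-dependent prior (0.0337).

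The authors' p-values gave 953 to 3947 probe sets at an unadjusted p under 0.05 in their 6 comparisons, and 0 after Benjamini-Hochberg adjustment. The group means mix genotype labels through the pools and include the 3 arrays with an opposing light score. These counts thus isolate neither genotype nor light.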
